A study of Bombyx mori with 2 samples.

How the data were processed

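Small non-coding RNAs of 50 to 500 nt were measured in the silkworm Bombyx mori, strain Dazao P50, on a 2-colour array. Per the labels, animals were raised after hatching at 25 °C in 14 h of light and 10 h of dark at 70% relative humidity. Total RNA was taken with Trizol and labelled with Cy3 and Cy5 while cDNA was made. Diapaused eggs (called embryo in the file headers) were set against the larva of instar 1, and pupae on day 1 of pupation against the larva of instar 5. Per the file headers, each of these 2 RNA pairs was hybridised in both dye orientations, once with the larva in Cy3 and once with the larva in Cy5, which gives 4 hybridisations. The labels name 1 sample per pair, so the spots and dye orientations of a pair are technical measurements of 1 RNA preparation per stage. No test between stages was made, and no p-value of this kind is given. The number of arrays limits the precision.

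Each array held 132 probes with names of the form Bm-number, each in 3 spots, besides control, blank and buffer spots, 561 spots in all. The deposited red and green signals are intensity values, Cy5 as R and Cy3 as G per the file headers. They are not whole numbers and were taken as background-corrected and normalized already, which is an inference. On the pupa arrays the negative control spots had a median Cy5 signal of 244 with the larva in Cy3 and 469 with the larva in Cy5, against 56.3 and 55.3 in Cy3, for a reason that was not tested. The mean Cy5 signals of blank and buffer spots were higher, 3865 and 4479 with the larva in Cy3. With the larva in Cy5 they were 1388 and 1525. With the larva in Cy3, Bm-111 and Bm-175, which had no usable spot, shared a mean pupal Cy5 signal of 7653. Their Cy3 signal was 56.3, the lowest of that channel. High Cy5 signals of such spots may therefore not measure background. Whether the Cy5 controls of the pupa arrays give a background level was not tested. The scanner, background correction and normalization tool are not given in the sources used here. Besides the signals, the authors deposited a flag score per spot and hybridisation, 0 or -50. The deposited log2 ratio of a spot equals the mean of log2(stage/larva) over the hybridisations flagged 0, and is absent where both are -50. The value table of the series holds the authors' log2 ratio per probe, the mean of these spot values, with a median of -0.03 for egg and -0.04 for pupa. Scale, direction and centring were therefore settled by comparison with the spots, and positive values mean more signal in egg or pupa than in the larva. The table and the spots share 131 probe names. The deposited p-value per spot matches a moderated t statistic that takes the hybridisations as replicates, with an infinite prior for egg and 16.1 prior degrees of freedom for pupa. The prior was fitted on spots usable in 1 hybridisation. With an infinite prior, the egg p-value sets a log2 ratio against 1 fixed SD of 0.31, and not against the spread of that spot. No biological spread enters the p-values of either pair.

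From the deposited signals, the log2 ratio of a probe was taken over spots with flag 0, first as the mean over spots within a dye orientation and then over orientations. The planned loess and normexp steps were not applied, because the signals were taken as normalized already. A probe was called higher or lower when its log2 ratio reached 1 in size (2-fold) and every measured spot and orientation had that sign. Errors are the technical SD over spots, each averaged over its usable orientations first, so a gap between orientations mostly does not enter them. The median of this SD was 0.11 in egg and 0.13 in pupa. The difference of the orientations divided by 2 had a median size of 0.16 and 0.17. The named probes were fixed by rule before the data were examined: up to 10 highest and 10 lowest called probes of each pair, and up to 10 called in opposite or in the same direction in both. The rule for probes dim in 1 channel could not be applied, since flags are given per spot and not per channel. Of the RNA classes fixed beforehand (snoRNAs, snRNAs, tRNAs, SRP RNA and others), none could be assigned, because the files used here give probe names without class, sequence or position. The names matched 0 entries of the RefSeq gene table for the assembly ASM3026992v2. No genome was used here. Of the fixed classes only the control messenger RNAs could be read, by name.

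The same calculation was tested on simulated data with the real flags. At 2-fold, 9 of 20 changed probes were recovered in the egg layout and 13 of 20 in the pupa layout, since the noise puts values on either side of the threshold. At 3-fold and 8-fold, all 20 were recovered in both layouts, and none in the wrong direction. Of the unchanged probes, 0 were called in each egg simulation and 1 in the pupa simulation at 2-fold. The simulation added the true ratio, a dye term and noise of 1 size per pair to the log2 ratios. It held no background, signal floor or detection ceiling, so it does not show the recovery for dim or saturated probes. The alternatives fixed beforehand that were run are median centring, centring on the control messenger RNA and control_ph probes, keeping flagged spots, each dye orientation alone, leaving out each spot, the median over spots, the authors' value table, thresholds of 1.5-fold and 3-fold, and no sign requirement. Added after seeing the data were a refitted loess (span 0.3), a limit to probes with all spots at flag 0, leaving out orientations at the detection ceiling, and raising dim egg-array signals to the 95th percentile of the negative controls. A probe was taken to be at the ceiling when all 3 spots lay within 10% of the highest signal of a channel together with at least another probe. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6 were used.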

Results

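The data describe small non-coding RNAs across 2 developmental transitions of the silkworm, from egg to larva and from larva to pupa. The egg RNA came from diapaused eggs, in which development is arrested, and was compared with the larva of instar 1. The pupal RNA came from day 1 of pupation and was compared with the larva of instar 5. Each pair was measured on 2 arrays with exchanged dyes, with 3 spots per probe. In the egg pair, 119 of 132 probes had at least 1 usable spot, and 96 were usable in both dye orientations. In the pupa pair, these numbers were 115 and 87. Usable spots made up 61.6% and 84.6% of the 396 spots on the egg arrays, and 74.5% and 58.8% on the pupa arrays, with the larva in Cy3 and in Cy5 respectively. Over probes usable in both orientations, the log2 ratios of the orientations correlated at r = 0.92 for egg and r = 0.62 for pupa (rho = 0.85 and 0.52). These correlations are across probes, which are not independent replicates. There was 1 RNA preparation per stage, so every difference below lacks a biological replicate.

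Most of the probes were not called different between egg and larva of instar 1. They are not shown to be unchanged. The simulation recovered 9 of 20 changes of 2-fold in this layout, a size at the threshold itself, and it held no signal floor. In the larval Cy3 channel, the 95th percentile of the negative controls was 825, against a median of 899 in usable spots. Of 119 probes, 8 were at least 2-fold higher in egg, 3 were at least 2-fold lower, and 108 were not called. The middle 50% of probes lay between -0.22 and 0.34 on the log2 scale. The largest difference by far was Bm-86, which was lower in egg, with a log2 ratio of -6.04 ± 0.77 (technical SD over 3 spots). Its egg signal was below the 95th percentile of the negative control spots, so the size of this difference is uncertain, as given below. Bm-23 was also lower in egg, with a log2 ratio of -1.85 ± 0.04, or 3.61-fold.

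Among the 8 probes higher in egg, Bm-160 had the highest log2 ratio, 1.61 ± 0.08. Bm-159 followed at 1.36 ± 0.67, with the widest spread between spots of the 8, from 0.59 to 1.83. Bm-180 stood at 1.35 ± 0.19, Bm-174 at 1.33 ± 0.09 and Bm-140 at 1.31 ± 0.04. Bm-151 at 1.11 ± 0.13, Bm-183 at 1.09 ± 0.14 and Bm-152 at 1.08 ± 0.08 were just past the 2-fold threshold. All 8 had the same sign in both dye orientations. The orientations lay close together for Bm-151, at 1.08 with the larva in Cy3 and 1.14 with the larva in Cy5. They lay further apart for Bm-159, at 1.97 and 0.76, for Bm-180, at 1.78 and 0.93, and for Bm-140, at 1.08 and 1.54. The errors given above do not hold these gaps. With the dim signals of the egg arrays raised to the 95th percentile of the negative control spots, Bm-151, Bm-160, Bm-180 and Bm-183 were still called, Bm-160 at 1.16 and Bm-180 at 1.05, and the other 4 were below the threshold.

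The size of the Bm-86 ratio depended on signals at the edges of the measured range. Its mean egg signal was 167 in Cy5, on an array where the lowest Cy5 signal was 149, against a larval signal of 29927. With the dyes exchanged, the egg signal was 176 and the larval signal 5444. The mean of the spot log2 ratios was -7.14 in the first orientation and -4.95 in the second. With the raised dim signals, the mean over the orientations was still -4.65, or 25.0-fold lower in egg on the deposited scale. This bounds that mean only and not the ratio in each orientation. The third lower probe, Bm-13 at -1.11 ± 0.08, rested on 2 spots in 1 dye orientation. With the same raised signals its log2 ratio was 0.0065, so that a difference could not be sized for it.

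**Figure D1:**
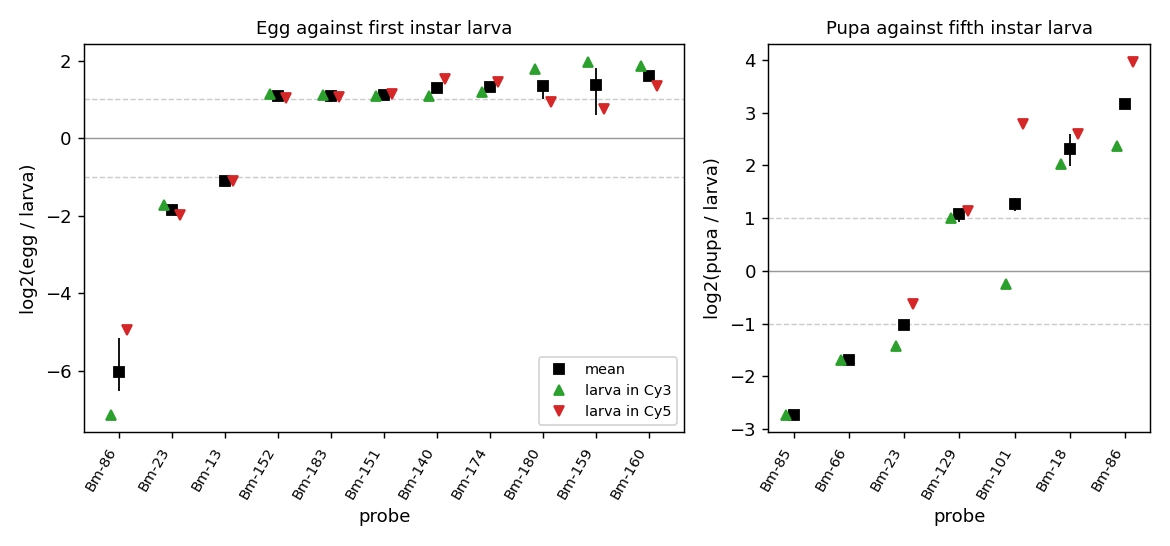
Log2 ratios of the probes called at least 2-fold different in egg against the larva of instar 1 (left) and pupa against the larva of instar 5 (right), with Bm-101 added on the right; squares are means, vertical lines the range over spots, and triangles the 2 dye orientations. Bm-86 lies at -6.04 on the left and 3.16 on the right, and the orientations of Bm-101 lie apart at -0.25 and 2.79.

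Between the larva of instar 5 and the pupa, again, few probes were called. In Cy5, the median signal of usable spots was 1.22 times the negative control median for the larva and 1.92 times for the pupa. A probe that was not called is therefore not shown to be unchanged. Bm-86 was higher in pupa, with a log2 ratio of 3.16 ± 0.07 (technical SD over 3 spots). Its pupal signal was at the detection ceiling in 1 orientation, which may lower this value. It was 2.45 with a refitted loess and 2.90 with centring on the controls. Bm-18 was higher at 2.31 ± 0.31 (4.97-fold), and Bm-129 at 1.07 ± 0.12. The larval Cy5 signal of Bm-129 was 374, below the median of 469 in the negative control spots of that channel, so the size of its ratio is uncertain. That of Bm-18 was 1367, above this median but no higher than the mean of 1388 in the blank spots of that channel. Whether these blank signals measure background is not settled, and the size of the Bm-18 ratio is left uncertain as well. Bm-23 was lower at -1.02 ± 0.07 (2.03-fold). Of 115 probes, 3 were higher, 3 were lower and 109 were not called, and the middle 50% lay between -0.31 and 0.25.

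The other lower probes in pupa were Bm-85 at -2.73 and Bm-66 at -1.69. Each rested on a single spot in 1 dye orientation, so no technical error can be given for them. The pupal signal of that spot was 49.5 for Bm-85 and 42.2 for Bm-66, below the median of 244 in the negative control spots of the same channel. In the larval channel that median was 56.3. The pupal signals were thus not above background by this measure, and the ratios are not reliable sizes. Dim signals were raised on the egg arrays only, so these calls were not put to that check. With flagged spots kept, Bm-85 was at -0.65 and Bm-66 at -0.26, and neither was called. With a refitted loess, Bm-66 was at -0.035 and not called, and Bm-85 was still called at -1.88. That spot was the third listed of the 3 for both. Without the third spots, neither probe had a value and Bm-23 stood at -0.99, so that none of the 3 lower probes was called. Bm-44 and Bm-64, named after the values were seen, were then called lower in their place. Bm-23 stood at -1.42 with the larva in Cy3 and at -0.62 with the larva in Cy5, a wider gap than between its spots. Bm-18 was steadier, at 2.03 and 2.59.

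The pupal signal of Bm-86 was at the detection ceiling in the first orientation. Its 3 Cy5 spots differed with a coefficient of variation of 0.18%, against 9.87% for the larval channel of the same spots. The log2 ratio of 2.36 in that orientation may therefore be limited by the ceiling, and the other orientation gave 3.96. The difference of the orientations divided by 2 was -0.80 here and -1.09 in the egg pair, with the same sign. A dye bias of this probe was thus not told apart from the ceiling as a source of the gap. Bm-101, picked out after its values were seen, was at the ceiling in both channels of the first orientation, where its ratio was -0.25. In the second orientation it was at 2.79, with a pupal signal of 57506 against 8147 in the larva. The highest larval Cy5 signal on that array was 9977, so this ratio may be limited as well. The mean of Bm-101, 1.27, passed the 2-fold threshold, but the probe was not called, because the orientations differed in sign. On the egg arrays, Bm-101 and Bm-33 were at the ceiling of at least 1 channel in both orientations, which limits the ratios that could be measured there.

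The technical error was gauged by the dye contrast, the difference of the orientations divided by 2, under the same rule. The sign had to be shared by all spots usable in both orientations. In each pair 1 probe passed it, Bm-86 in the egg pair and Bm-101 in the pupa pair, against 10 and 4 probes called in both orientations for the stage difference. Bm-47 in the pupa pair, picked out after its values were seen, also had a contrast past 1 in size, at -1.19. It did not pass, because no spot of it was usable in both orientations. In the authors' deposited table, all spots of 26 of the 119 egg probes and of 11 of the 115 pupa probes had an unadjusted p-value below 0.05. Over spots, 107 of 345 in the egg table and 52 of 313 in the pupa table were below 0.05, and after Benjamini-Hochberg adjustment 86 and 18 were. The deposited p-values set the log2 ratios of these hybridisations against 0 without biological spread, so they are not a test between stages.

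The counts depended on what was taken as unchanged. Of the control messenger RNA spots, those named actinA3 (an actin) had 2 usable spots of 12 in the egg pair and 0 in the pupa pair. Those named RpL3 (a ribosomal protein) had 1 usable spot of 12 in each pair. The control named control_ph, whose role the files do not state, was usable in all 12 spots in at least 1 orientation, with a log2 ratio of 0.58 ± 0.25 in egg and 0.30 ± 0.15 in pupa. With each array centred on these controls, the median of all probes was -0.43 in egg and -0.29 in pupa. This centring rested mainly on control_ph. It was the only control usable with the larva in Cy3 in egg and with the larva in Cy5 in pupa. The calls were then 1 higher and 11 lower in egg, and 2 higher and 6 lower in pupa. Bm-86, Bm-23, Bm-160 and Bm-18 were called in the same direction under this centring in the pairs given above. Under it, Bm-140, Bm-151, Bm-152, Bm-159, Bm-174, Bm-180 and Bm-183 in egg, and Bm-129 in pupa, fell below the 2-fold threshold.

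The transitions shared few called probes. Bm-86 was the only probe called in opposite directions, lower in egg and higher in pupa than in the larva of each pair. Bm-23 was the only probe called in the same direction, lower in both. Among the 111 probes measured in both pairs, 7 were called higher and 2 lower in egg, and 3 higher and 2 lower in pupa. Independent lists of these sizes would share 0.18 probes in opposite directions and 0.23 in the same direction. Bm-18, higher in pupa, had a log2 ratio of -0.83 ± 0.18 in egg, short of the threshold. Of the probes higher in egg, Bm-160 was at -0.04 ± 0.22 in pupa and Bm-183 at -0.35 ± 0.14. Bm-151 was at 0.60 ± 0.10 in pupa, with the sign it had in egg. The larval Cy5 signals of Bm-160 (341) and Bm-151 (393) on the pupa arrays were also below the negative control median of 469.

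Across the 111 probes the log2 ratios of the transitions correlated with Pearson's r = -0.33 and Spearman's rho = 0.14. These values are across probes, which are not independent replicates. The negative r rested on Bm-86. Without it r was 0.06 and rho was 0.17, and without Bm-86 and Bm-23, the probes farthest from the median egg ratio, r was 0.0014 and rho 0.15.

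**Figure D2:**
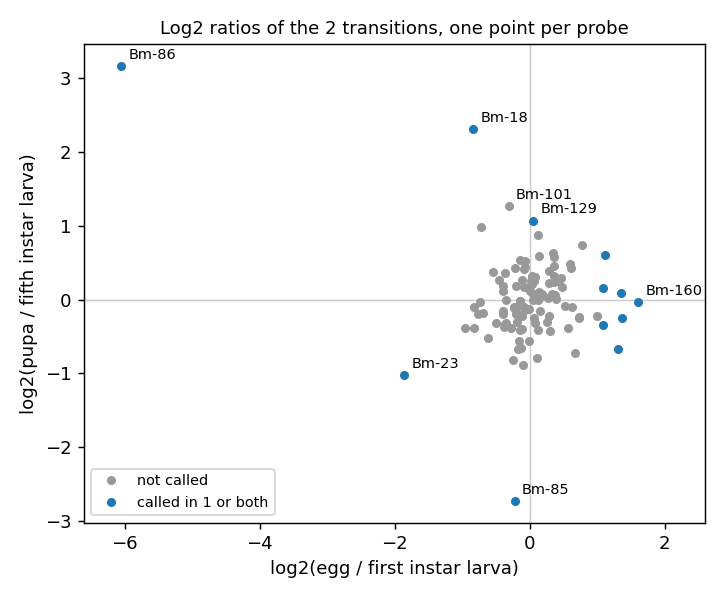
Log2 ratio of egg over the larva of instar 1 (x axis) against log2 ratio of pupa over the larva of instar 5 (y axis) for the 111 probes measured in both pairs, one point per probe; blue points were called in at least 1 pair. Bm-86 lies alone at the upper left, at -6.04 and 3.16, and the other points show no common slope (r = 0.06 without it).

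Some probes were usable in 1 pair only. Of 132 probes, 111 were measured in both pairs, 8 only in the egg pair, 4 only in the pupa pair and 9 in neither. Bm-83 and Bm-174 were usable in all 3 spots and both orientations in the egg pair and in no spot of the pupa pair. Bm-65 was usable in all of them in the pupa pair, with a log2 ratio of 0.02 ± 0.20 from Cy5 signals below the negative control medians, and in none in the egg pair. A probe without a usable spot had both orientations flagged in every spot. What set the flag is not given in the sources used here, so such a probe is not shown to be undetected or absent. Signals were not compared between the pairs, which were hybridised on different arrays.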

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

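For Bm-86 and Bm-101, the tests of dye bias, single spots and the detection ceiling were chosen only after the results were seen. The test of the egg signal floor was set down before its result.

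Bm-86 was lower in egg (-6.04, a size that rests on an egg signal below the 95th percentile of the negative controls) and higher in pupa (3.16, or 2.45 with a refitted loess) than in the larva of the same pair, in every spot and dye orientation. That the transitions differ was not tested, because each has 1 RNA preparation per stage. A dye bias alone would turn the sign with the dyes, but a call already required 1 sign, so the sign decides nothing. The smallest of the 4 orientation means was 2.36 in the direction of its transition, a size that the call did not require. A dye bias in part of the size is not excluded, since the dye contrast was -1.09 in the egg pair and -0.80 in the pupa pair. A single aberrant spot is argued against by the smallest of the 6 spot values, 3.08. The egg signal floor accounts for part of the size only, since the ratio was -4.65 with the egg signal raised to the negative controls. A difference between the stages and one between these particular RNA preparations both stay open and untested.

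Bm-101 in the pupa pair had opposite signs in the dye orientations, -0.25 and 2.79. A detection ceiling in the first orientation may account for the value near 0 there: its lowest spot was at 98.6% of the highest signal of the channel, and the second orientation was below the ceiling. A dye bias of this probe cannot be told apart from it, because the egg arrays, where the contrast was 0.015, were at the ceiling too. Larval Cy5 in the second orientation may be limited as well. Its highest signal was 9977, with Bm-101, Bm-33 and Bm-68 at 8147, 7146 and 8334, against 42700, 42713 and 24474 in larval Cy3. Even if the ceiling is the cause, 2.79 is thus not shown to be a sound size. A higher level in pupa stays a hypothesis resting on 1 hybridisation.

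In all, 16 Bm probes had every spot and orientation of the pairs on opposite sides of 0, and 28 on the same side, none of them tested as a difference. Besides Bm-86, those among the probes called in a pair were Bm-18, Bm-159 and Bm-183. Bm-18 was at -0.83 in egg and 2.31 in pupa. Bm-159 was at 1.36 and -0.25, the latter from 2 spots in 1 orientation, and Bm-183 at 1.09 and -0.35.

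Signal was also seen outside the Bm probes compared above. The control_ph spots had a log2 ratio of 0.58 in egg and 0.30 in pupa. A single blank spot of 48 on the egg arrays carried a usable value, 0.997, from 1 orientation. AP-5, a probe whose role the files do not state, had a mean of -1.22 in pupa from 2 spots, at -2.18 and -0.26. The value table lists Bm-110 at -0.50 for egg, and the spot tables used here hold Bm-111 in place of that name, without a usable spot.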

How the results depend on the processing

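The alternatives of refitted loess, full spot sets, ceiling, raised dim signals and leaving out 2 probes were chosen after seeing the data. Higher calls in egg (8) were 1 with centring on the controls, 17 at 1.5-fold, 1 at 3-fold and 4 with raised dim signals. Lower calls in egg (3) were 11 with centring on the controls, 12 with flagged spots kept, 12 at 1.5-fold and 5 with the larva in Cy5 alone. Higher calls in pupa (3) were 5 with flagged spots kept, 7 with the larva in Cy5 alone and 9 at 1.5-fold. Lower calls in pupa (3) were 6 with centring on the controls, 1 with flagged spots kept, 1 with full spot sets, 9 at 1.5-fold, 7 with the larva in Cy3 alone and 0 with the larva in Cy5 alone. The correlation of the transitions was -0.089 with flagged spots kept, -0.45 with full spot sets, 0.14 as Spearman's rho and 0.0014 without Bm-86 and Bm-23. Probes called in the same direction in both (1) were 0 with the larva in Cy5 alone, 3 at 1.5-fold, 0 at 3-fold, and between 0 and 1 when each spot was left out in turn. Those called in opposite directions (1) were 2 with centring on the controls, 2 in each dye orientation alone and 4 at 1.5-fold. Bm-13 in egg turned from -1.11 to 0.0065 with raised dim signals. Fewer or dimmer values tested, or a moved threshold or centre, are built into these alternatives, and beyond that the cause was not tested. All other counts stayed within 1.5 times. Of the values under the alternatives of named probes with more than 1 spot, 157 moved by less than the spread between spots, 45 by more, and 1 changed sign. Without the third spots, 2 other probes and none of the 3 were called lower in pupa. Other background corrections, no normalization and a limit of signal at least 2 times background had been intended and were not run, for want of background and raw columns here, nor were the medians of RNA classes. Flags limited 23 egg and 28 pupa probes to 1 dye orientation. No paired analysis was possible because each pair has 1 sample.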

Other observations

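The numbers of the probes went with the egg ratio, a pattern noticed in the data. The tests of dye bias and signal intensity below were set down before their results, and the test of position after. Of the 21 measured probes numbered 150 or above, 19 had a log2 ratio above 0 in egg, with a median of 0.61, against 41 of the 98 lower-numbered probes, with a median of -0.08. Of the 8 probes called higher in egg, 7 were among these 21, and the 14 that were not called had a median of 0.39. Both the calls and the choice of numbers rest on the same egg ratios, so this adds no separate support.

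What the numbers stand for is not given in the sources used here. A position effect shared by all slides was not seen in the 19 of these probes measured in pupa, whose rows have the same order and whose median was 0.093. Row order is not shown to be slide position. The pupa pair was on other arrays, so an effect of the egg slides alone stays open. Bm-158 and Bm-174, the latter called higher in egg, had no usable spot in the pupa pair. The lower of the orientation medians was 0.41, which had been set to count against a dye bias. The numbers had been picked for high means over these same orientations, so this does not decide it. Signal intensity stays open too. The observed median was above 100% of 10000 random lists matched on intensity, which had been set to count against intensity. The numbers had been picked for their high ratios, a flaw seen only after the result, so this decides nothing. The median was 0.45 after a refitted loess and 0.09 with centring on the controls, where the median of all probes was -0.43. A candidate explanation is that the numbers group RNAs of a kind or origin that is more abundant in egg RNA relative to the rest, which was not tested here.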
